A study of Homo sapiens with 4 samples.

How the data were processed

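RNA-seq was done on U2OS osteosarcoma cells with a GREM1 knockdown and on control cells, with 2 libraries per group. Per the labels' protocols, RNA was isolated with the RNeasy mini plus kit, and 1.3 ug of total RNA per sample went into libraries made with the SMARTER mRNA-Seq kit. The deposited table holds raw counts per gene. The submitters' processing notes name HISAT2 2.0.5, StringTie 1.3.3b and DESeq2, the last with no version, and do not say which of them made the deposited counts. The program that counted the reads and its strand setting are not given in the sources used here, so the counts of overlapping genes may share reads, as for JUNB with HOOK2, ETV4 with DHX8, CRIM1 with FEZ2, RPLP2 with PIDD1 and UNC5B with UNC5B-AS1. The same notes name the mouse build mm10, but the table is human: all 58735 genes matched GENCODE 29 (Ensembl 94, GRCh38) in identifier, start, end, strand, symbol and biotype. The table's columns carry abbreviations, and NC1, NC2, SHG11 and SHG12 were read as shControl-1, shControl-2, shGREM1-1 and shGREM1-2 from the abbreviation alone. The results of 1 gene list and of single genes withheld for evaluation are not reported here. Only this table was analysed, and its 4 count columns were all used.

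Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 18442 genes, and libraries were scaled by TMM, with factors of 0.987, 0.9987, 1.005 and 1.01. A quasi-likelihood model with the group alone was fitted with robust estimation, and genes with a Benjamini-Hochberg adjusted p under 0.05 over all kept genes are said to have risen or fallen. Log2 fold changes are shGREM1 minus shControl, and their SE was worked out from the F statistic. CPM values are scaled by the TMM factors unless they are given for GREM1. Named genes were GREM1, the 10 largest rises and 10 largest falls among protein-coding genes with a mean CPM of 10 or more and no overlap between the groups, up to 4 members of each called list that changed in its direction or of each BMP or osteoblast list, and up to 2 members of each other list not called. Other list members that passed are named beside them. SCG5, FMN1, SAA2 and RELA, and the list members ID1, ID3, SMAD6, SMAD7, CXCL8, MMP9, PTPRC and CD74 that did not pass or were not kept, were added outside the rule after the results were seen.

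The 34 lists of genes, the tests, the rule for named genes and all alternatives except 1 were fixed before the data were examined. Lists with at least 5 kept members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation, camera on ranks and fry were alternatives. Other alternatives were relative log expression, upper-quartile and total count scaling, no count filter, a mean CPM filter of 5, DESeq2 1.42.0, limma-voom, protein-coding genes only, no robust estimation, a replicate block, glmTreat against 1.5-fold and leaving out each library in turn, where the lone library is assumed to vary like the other group. In fits without 1 library, the spread comes from the other group alone. An adjusted p or call gained in them is therefore not evidence of a change. A correction of each library for gene length and GC content, by natural splines with 4 degrees of freedom, was added after the results were seen.

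The biological coefficient of variation was 11.4%, and the median absolute log2 difference between libraries of a group was 0.173 for shControl and 0.194 for shGREM1. The script was tested on simulated counts of the 18442 genes for this comparison: it recovered 35.8% of 67 genes changed 1.5-fold, 68.7% of 67 changed 2-fold and 84.9% of 66 changed 4-fold. Of its calls 2.33% were false, and 0 lists were called on unchanged data. The simulated counts were drawn independently for each gene, with dispersions taken from the trend. The simulation therefore could not show false list calls that arise from correlation between genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.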

Results

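Gene expression was measured by RNA-seq in U2OS cells, an established human osteosarcoma line, in a series that compares cells with a knockdown of GREM1 against control cells. GREM1 encodes gremlin 1, a secreted antagonist of bone morphogenetic proteins (BMPs). The series holds 2 control libraries, labelled shControl, and 2 knockdown libraries, labelled shGREM1. The deposited table gives raw read counts for 58735 genes in each of the 4 libraries. The totals were 15676556 and 15492826 counts in shControl-1 and shControl-2, and 16353015 and 15968817 in shGREM1-1 and shGREM1-2. Between 28109 and 29097 genes had at least 1 count in a library. The labels do not say whether samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

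The targeted gene was close to undetected in every library. GREM1 (ENSG00000166923, chromosome 15, 32717974 to 32745107, plus strand, GRCh38) had 2 counts in shControl-1, 0 in shControl-2, 1 in shGREM1-1 and 1 in shGREM1-2. Exact 95% Poisson intervals, which cover counting error only, reached from 0.242 to 7.22 counts in shControl-1 and from 0.0253 to 5.57 counts in each shGREM1 library. In shControl-2, the count of 0 had an upper limit of 3.69 counts, or 0.238 CPM. Both groups summed to 2 counts, of 31169382 counts in shControl and 32321832 in shGREM1. A difference in GREM1 was not detectable at this depth, and no fold change is given. The knockdown that the labels name could not be checked from these counts. Because shControl also held almost no GREM1 reads, the differences described below cannot be assigned to a loss of GREM1. SCG5 (ENSG00000166922), which lies 20.9 kb from GREM1 and encodes the neuroendocrine protein 7B2, fell by 1.48 ± 0.26 on the log2 scale (SE; edgeR adjusted p = 0.00309), with 124 and 153 counts in shControl against 59 and 45 in shGREM1. FMN1, 20.4 kb away on the other side, had 263 and 384 counts in shControl and 218 and 360 in shGREM1.

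**Figure D1:**
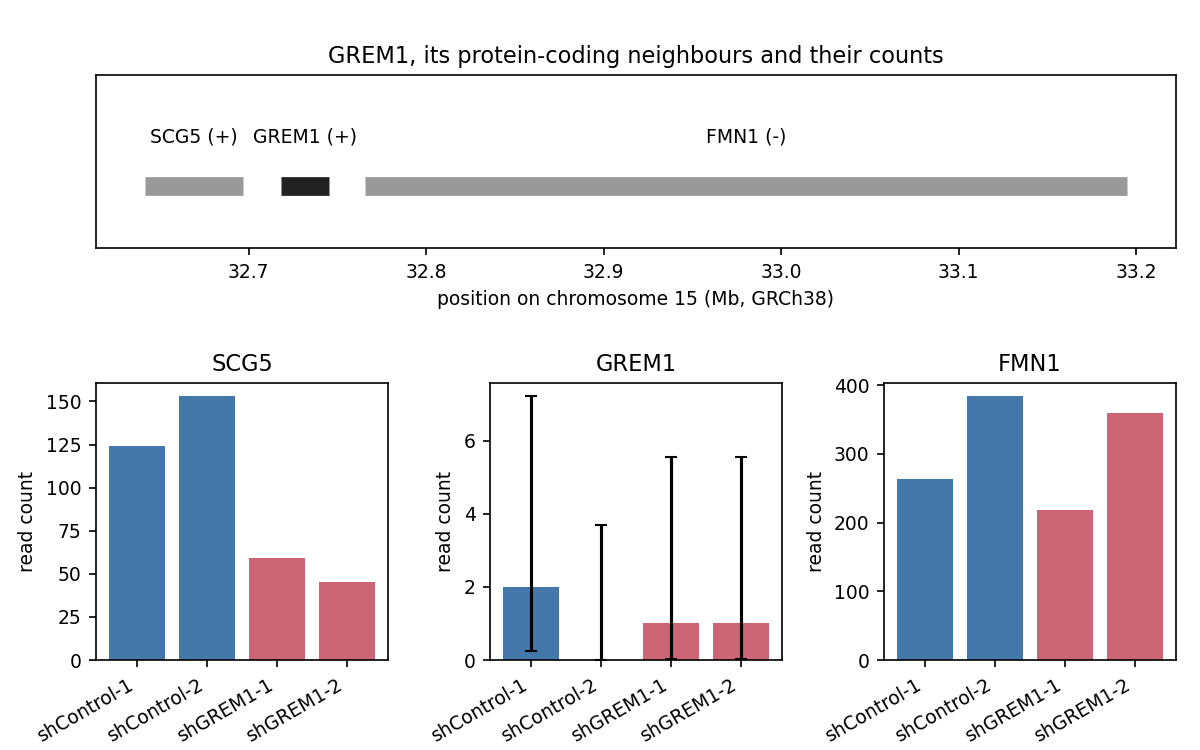
Top, GREM1 and its protein-coding neighbours SCG5 and FMN1 drawn to scale on chromosome 15 (Mb, GRCh38), with the strand in parentheses. Bottom, read count of each gene in the 4 libraries (bars; blue shControl, red shGREM1), with exact 95% Poisson intervals for GREM1: GREM1 had between 0 and 2 counts, while SCG5 had 124 and 153 counts in shControl and 59 and 45 in shGREM1.

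The comparison of shGREM1 with shControl asks which transcripts differ between the knockdown and control cells. Among protein-coding genes with a mean of at least 10 CPM, the largest falls in shGREM1 were in the acute-phase protein gene SAA1, the cytokine genes CSF2 and IL1B, the gamma-glutamyltransferase gene GGT5 and the pentraxin gene PTX3. The largest rises among them were in the microtubule protein gene MAP2, the collagen gene COL3A1 and the cyclin-dependent kinase gene CDK14. Of 18442 genes kept after the count filter, 659 were higher and 759 lower in shGREM1 by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p below 0.05. The balance between them depended on library scaling, with 793 higher and 631 lower under upper-quartile scaling. At least 2-fold changes accounted for 165 of the higher and 187 of the lower genes. Protein-coding genes made up 559 of the higher and 708 of the lower genes. The first principal component, with 53.8% of the variance, separated the groups, and the second, with 25.5%, separated the shGREM1 libraries from each other. These counts depended on the libraries: without shControl-1 there were 266 higher and 382 lower genes, without shControl-2 389 and 466, and without shGREM1-1 998 and 1112. The counts of at least 2-fold changes were 96 higher genes without shControl-1, 267 higher and 326 lower without shGREM1-1, and 286 lower without shGREM1-2.

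**Figure D2:**
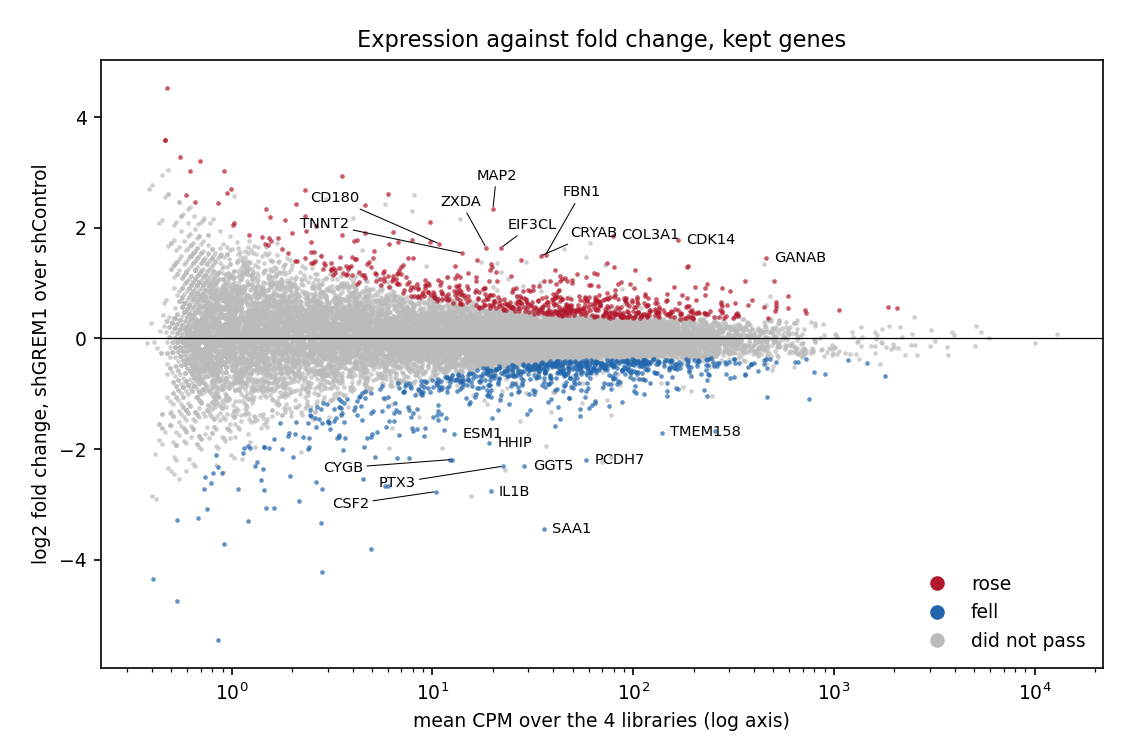
Log2 fold change of shGREM1 over shControl against the mean CPM of the 4 libraries (log axis) for the 18442 kept genes. Red points rose (659), blue points fell (759) and grey points did not pass; the 10 largest rises and 10 largest falls named by the rule are labelled, from MAP2 at 2.34 to SAA1 at -3.44.

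SAA1 (ENSG00000173432, chromosome 11, 18266174 to 18269977, plus strand) fell from 65.7 ± 3.29 CPM in shControl to 6.06 ± 1.09 CPM in shGREM1 (SD, n = 2 each), a log2 fold change of -3.44 ± 0.16 (SE; edgeR adjusted p = 9.39e-09). Its near-identical neighbour SAA2 had a log2 fold change of -3.82 (edgeR adjusted p = 2.25e-05), and reads could be split between them, so the value of each is uncertain. CSF2 (ENSG00000164400), which encodes the growth factor GM-CSF, fell from 18.1 ± 0.822 to 2.65 ± 0.0512 CPM (log2 fold change -2.77 ± 0.22, edgeR adjusted p = 3.43e-06). IL1B (ENSG00000125538) also had a log2 fold change of -2.77, with a larger spread in shControl (34.0 ± 15.3 CPM) than in shGREM1 (4.99 ± 0.281 CPM). The other falls were in GGT5 (-2.31), PTX3 (-2.31), the protocadherin gene PCDH7 (-2.19), the globin gene CYGB (-2.19), HHIP (-1.89), an inhibitor of hedgehog ligands, ESM1 (-1.73) and TMEM158 (-1.70). HHIP overlaps HHIP-AS1, and the counts of such partners may not be separable because no strand setting is given. ESM1 no longer passed without shControl-1 (edgeR adjusted p = 0.278) or without shControl-2 (0.23). ESM1 also did not pass with a mean CPM filter of 5 (0.0621) or among protein-coding genes only (0.0583).

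MAP2 (ENSG00000078018, chromosome 2, 209424058 to 209734118, plus strand) rose from 6.57 ± 2.06 CPM in shControl to 33.3 ± 9.26 CPM in shGREM1 (SD, n = 2 each), 5.07-fold (log2 fold change 2.34 ± 0.26, edgeR adjusted p = 0.000952). COL3A1 (ENSG00000168542) rose 3.62-fold, from 34.2 ± 8.66 to 124 ± 27.2 CPM. CDK14 (ENSG00000058091) rose 3.44-fold, from 75.3 ± 1.69 to 259 ± 27.6 CPM, and overlaps CLDN12, which is expressed at a mean of 77.6 CPM. The fibrillin gene FBN1 (log2 fold change 1.51), the small heat shock protein gene CRYAB (1.49) and GANAB (1.45), which encodes the alpha subunit of glucosidase II, rose as well. GANAB was the most abundant of these, at 246 ± 15.4 CPM in shControl and 671 ± 12.1 CPM in shGREM1. ZXDA and EIF3CL both had a log2 fold change of 1.64, but each has a near-identical paralog, ZXDB and EIF3C, and is uncertain. CD180 (1.71) no longer passed without shControl-1 (edgeR adjusted p = 0.101), and the cardiac troponin gene TNNT2 (1.54) no longer passed without shControl-1 (0.317) or shControl-2 (0.311), with a mean CPM filter of 5 (0.0546) or after a length and GC correction (0.0624).

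**Figure D3:**
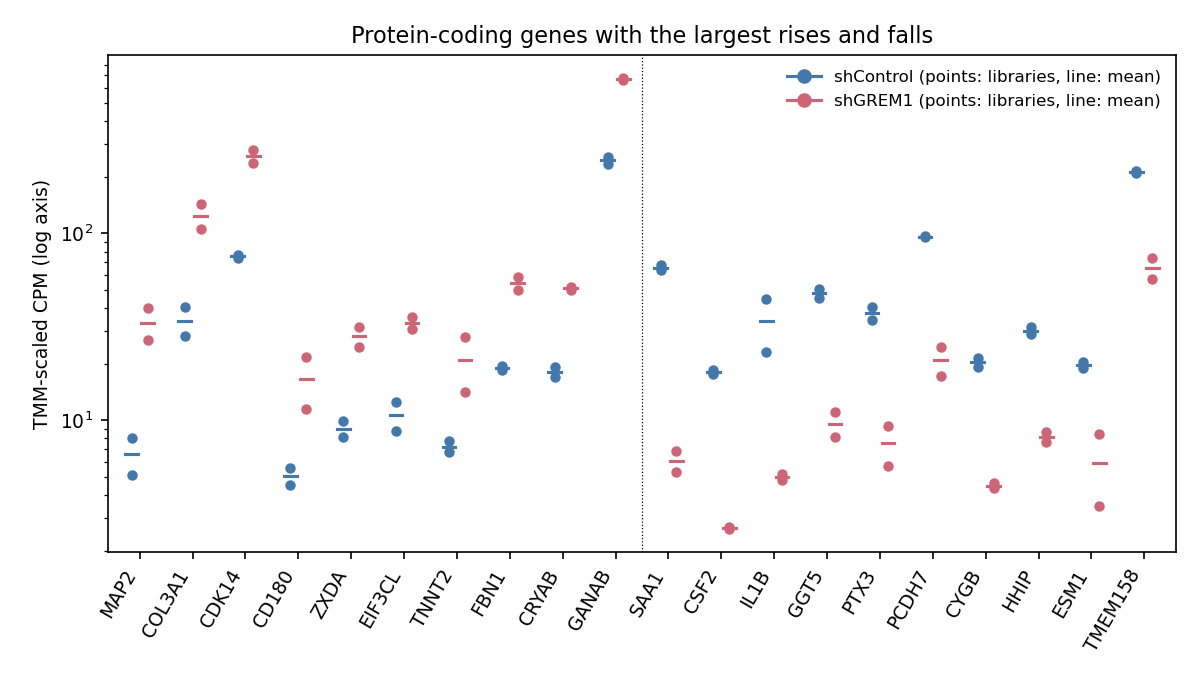
TMM-scaled CPM (log axis) of the 10 protein-coding genes, of those with a mean of at least 10 CPM, with the largest rises (left of the dotted line) and the 10 with the largest falls (right). Points are libraries and lines are group means, blue for shControl and red for shGREM1; SAA1 went from a mean of 65.7 CPM to 6.06 CPM and MAP2 from 6.57 CPM to 33.3 CPM.

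Genes of NF-kB signalling and its cytokines were lower in shGREM1. Of 25 measured members, 15 fell, 1 rose and 9 did not pass, and 20 fell and 1 rose when adjusted over the list alone. The median log2 fold change was -1.23, and 23 of the 25 lay below 0. Beside CSF2 and IL1B, the falls included TNFAIP3 (log2 fold change -1.40 ± 0.14), a feedback inhibitor of NF-kB, the macrophage growth factor gene CSF1 (-1.23 ± 0.12), the receptor gene IL7R (-1.25 ± 0.14) and the NF-kB subunit genes NFKB2 (-0.68) and RELB (-0.78). The chemokine gene CCL2 went the other way, at 167 and 146 CPM in shControl and 242 and 373 CPM in shGREM1 (log2 fold change 0.98, edgeR adjusted p = 0.0436). CXCL8, the interleukin 8 gene, had 90.1 and 162 CPM in shControl and 35.6 and 21.3 CPM in shGREM1 and did not pass (edgeR adjusted p = 0.156). RELA, which encodes a main NF-kB subunit, had a log2 fold change of -0.01 (edgeR adjusted p = 0.966). The list was called lower by camera with a preset correlation (limma, adjusted p = 2.3e-11), and it had an adjusted p = 0.466 with an estimated correlation. CCL2 did not rise without shControl-1 or without shControl-2, where 0 members of the list rose.

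Target genes of BMP and SMAD signalling were lower in shGREM1 as a list. Gremlin 1 opposes this pathway, so its loss would be expected to raise them rather than lower them. With almost no GREM1 reads in either group, the fall cannot be tied to GREM1. Of 18 measured members, 4 fell, 0 rose and 14 did not pass, with the same 4 falls adjusted over the list alone. The 4 were SNAI2 (log2 fold change -1.14 ± 0.17), a transcriptional repressor, the netrin receptor gene UNC5B (-0.88 ± 0.17) and the transcription factor genes ID2 (-0.96 ± 0.23) and MSX1 (-0.62 ± 0.15). ID1, a direct SMAD target, had 330 and 338 CPM in shControl against 220 and 103 CPM in shGREM1 and did not pass (log2 fold change -1.05 ± 0.48, edgeR adjusted p = 0.364). ID3 likewise had 121 and 104 CPM against 62.2 and 23.9 CPM (edgeR adjusted p = 0.376), and the inhibitory SMAD genes SMAD6 and SMAD7 had log2 fold changes of -0.47 and 0.03 without passing. The list median was -0.628, and camera called the list lower (limma adjusted p = 0.000143), with an adjusted p = 0.466 with an estimated correlation. When single libraries were left out, the list median ran from -0.477 without shGREM1-2 to -0.788 without shControl-1. ID2 no longer passed without shControl-2 (edgeR adjusted p = 0.0785) or shGREM1-2 (0.0593), nor MSX1 without shControl-1 (0.122) or shGREM1-2 (0.0569).

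BMP ligands and receptors went both ways. Of 26 measured members, BMP5 (log2 fold change 0.50) and the receptor gene BMPR1A (0.45) rose, BMP4 (-0.42) fell and 23 did not pass, with the same counts adjusted over the list alone, and camera did not call the list (limma adjusted p = 0.132). The type I receptor gene ACVR1 had a log2 fold change of -0.37 (edgeR adjusted p = 0.0782). Among 11 other BMP antagonists, follistatin (FST) fell from 106 ± 5.92 to 59.7 ± 12.1 CPM (SD, n = 2 each; log2 fold change -0.83 ± 0.13, edgeR adjusted p = 0.00178), and CHRD (0.44), CRIM1 (-0.47), SOSTDC1 (0.58) and 7 more did not pass. Adjusted over the list alone, 1 of them fell and 0 rose, and the list was not called (limma adjusted p = 0.75). Without shControl-1, the edgeR adjusted p was 0.103 for BMP5, 0.237 for BMP4 and 0.189 for BMPR1A. Without shControl-2 it was 0.0617 for BMP5 and 0.134 for BMPR1A, and without shGREM1-2 it was 0.128 for BMPR1A and 0.036 for ACVR1. BMPR1A also did not pass with DESeq2 (adjusted p = 0.0952), limma-voom (0.053) or a length and GC correction (0.0604). CHRD passed after that correction (edgeR adjusted p = 0.0361), and CRIM1 passed with DESeq2 (0.048) and without a count filter (0.000815). The shGREM1 libraries differed for both genes. The log2 fold change was 0.602 for CHRD and -0.801 for CRIM1 without shGREM1-1, against 0.25 and -0.205 without shGREM1-2. Of the ligands and receptors, 0 rose without either shControl library, 5 fell without shGREM1-1, and 4 fell and 1 rose without shGREM1-2. Of the antagonists, 2 rose and 2 fell without shGREM1-1, and 2 fell without shGREM1-2. The ligand and receptor list was called lower without shControl-1 (limma adjusted p = 0.0339) and without shGREM1-2 (0.0436).

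Bone matrix genes were among the osteoblast genes that rose. Of 13 measured members of the osteoblast differentiation list, SPARC (872 ± 4.95 to 1250 ± 168 CPM), COL1A1 (596 ± 26.5 to 845 ± 115 CPM) and the low-level SPP1 (2.11 ± 0.778 to 5.81 ± 1.53 CPM; SD, n = 2 each) rose, 0 fell and 10 did not pass. Adjusted over the list alone, 3 rose and 1 fell. The alkaline phosphatase gene ALPL had a log2 fold change of -0.98 (edgeR adjusted p = 0.0888). The list's median (-0.108) and mean (0.123) differed in sign, the direction of the test followed the mean, and camera did not call it (limma adjusted p = 0.562). Without shControl-2, the edgeR adjusted p was 0.126 for SPARC, 0.166 for COL1A1, 0.102 for SPP1 and 0.026 for ALPL. SPARC and COL1A1 did not pass without shControl-1 either. The log2 fold change of ALPL was -0.598 without shGREM1-1 and -1.51 without shGREM1-2. ALPL passed without a count filter (edgeR adjusted p = 0.00113). Of the osteoblast list, 1 rose without shControl-1, 0 rose and 1 fell without shControl-2, 1 fell without shGREM1-1 and 3 fell without shGREM1-2. TGF-beta target genes went both ways: of 23, PMEPA1 (0.55) and NOX4 (1.27) rose, JUNB (-0.74), CDKN1A (-0.70) and TGIF1 (-0.38) fell, and 4 rose and 4 fell adjusted over the list alone (limma adjusted p = 0.77 for the list). Without shControl-1, 0 of the TGF-beta targets rose, without shControl-2 1 rose, without shGREM1-1 4 rose and 6 fell, and without shGREM1-2 4 rose.

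Regulators of apoptosis were lower in shGREM1 as a list, with changes in both pro- and anti-apoptotic genes. Among 24 apoptosis regulators, 6 fell and 2 rose, and 7 fell and 2 rose adjusted over the list alone. The pro-apoptotic genes BAK1 (log2 fold change -0.71), BAX (226 ± 9.46 to 152 ± 2.87 CPM; SD, n = 2 each), BID and BAD and the anti-apoptotic genes BCL2L1 (-0.44) and MCL1 (-0.45) were those that fell, while the pro-apoptotic BCL2L11 (0.73) rose. That list was called lower (limma adjusted p = 0.0239), with an adjusted p = 0.466 with an estimated correlation, and was not called without shControl-2 (0.0706). Without shControl-1, 2 of its members fell, and BID (edgeR adjusted p = 0.133) and BAD (0.263) no longer passed; without shControl-2, 4 fell. BAD overlaps the more abundant GPR137 (119 CPM) and is uncertain.

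Genes of cell division were higher in shGREM1, by small amounts. Of 44 measured mitosis and G2/M genes, 8 rose, 0 fell and 36 did not pass, 20 rose adjusted over the list alone, and 42 lay above 0 (median log2 fold change 0.283; camera, limma adjusted p = 8.66e-07; adjusted p = 0.466 with an estimated correlation). The kinetochore gene CENPF rose from 214 ± 7.44 to 336 ± 28.2 CPM (SD, n = 2 each), a log2 fold change of 0.65 ± 0.11. The proliferation marker MKI67 (0.44) and the cyclin gene CCNB2 (0.45) rose as well, but did not pass without shControl-1 or without shControl-2. Of 38 DNA replication and G1/S genes, MCM6 (0.43), MCM3 (0.42) and GINS2 (0.46) rose, as they did adjusted over the list alone, 35 did not pass and 36 lay above 0 (median 0.165; limma adjusted p = 0.000291; adjusted p = 0.569 with an estimated correlation). Of 10 measured replication-dependent histone genes, 6 rose, among them HIST1H4H (0.85 ± 0.13), HIST1H2BD (0.99 ± 0.17) and HIST1H2BK (0.58 ± 0.12), and 7 rose adjusted over the list alone (median 0.513; limma adjusted p = 0.000143; adjusted p = 0.466 with an estimated correlation). Histone genes of one family have similar sequences, so their separate values are uncertain. Only 10 of the 20 listed histone genes were kept in these libraries, which were made with an mRNA kit. Their rise is therefore not read as a sign of more cell division. The number of risen mitosis genes was 2 without shControl-1, 1 without shControl-2 and 15 without shGREM1-2. The number of risen replication genes was 1, 0, 6 and 5 without shControl-1, shControl-2, shGREM1-1 and shGREM1-2, and the replication list was not called without shControl-2 (limma adjusted p = 0.236). MCM6 had an edgeR adjusted p of 0.147 and 0.0902 without shControl-1 and shControl-2, MCM3 of 0.0925, 0.27 and 0.0638 without shControl-1, shControl-2 and shGREM1-2, and GINS2 of 0.278 without shControl-2 and 0.0714 with DESeq2. GINS2 overlaps the more abundant GSE1 (151 CPM) and is uncertain. The number of risen histone genes was 2 without shControl-1 and 3 without shControl-2, where HIST1H2BD had an edgeR adjusted p of 0.0557 and HIST1H2BK of 0.0525, respectively.

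Most ribosomal protein genes were slightly lower in shGREM1. Of 72 measured genes, 70 lay below 0 with a median log2 fold change of -0.245, and RPL35, RPL38, RPLP2, RPL7 and RPS15 fell, with 5 falls adjusted over the list alone and 0 rises. RPL35 had 518 ± 6.9 CPM in shControl and 377 ± 23.9 CPM in shGREM1 (SD, n = 2 each). The list was called lower (limma adjusted p = 3.46e-09), with an adjusted p = 0.516 with an estimated correlation. Of 39 nuclear genes of oxidative phosphorylation, ATP5MC1 (log2 fold change -0.73) and CYC1 (-0.47) fell, 2 fell adjusted over the list alone and 33 lay below 0 (median -0.187; limma adjusted p = 0.000197; adjusted p = 0.516 with an estimated correlation). The 13 mitochondrially encoded genes included 0 that passed, over all genes or over the list alone, and the list was not called (median 0.115; limma adjusted p = 0.28), except without shGREM1-2 (limma adjusted p = 0.00182), when 5 of them rose. Without shGREM1-1, 1 of them fell. Mitochondrial transcripts took 4.48% and 4.35% of counts in shControl and 5.38% and 4.24% in shGREM1. No ribosomal protein gene passed without shControl-1 or without shControl-2. The list median was -0.32 without shGREM1-1 and -0.158 without shGREM1-2. RPL38 (edgeR adjusted p = 0.0787) and RPLP2 (0.0682) did not pass without shGREM1-2. With upper-quartile scaling RPL38 (0.0537), RPLP2 (0.0565) and RPL7 (0.062) did not pass, nor did RPL7 with total count scaling (0.0523), RPLP2 (0.0521) and RPL7 (0.0544) without robust estimation, or RPLP2 after a length and GC correction (0.0939). Neither ATP5MC1 nor CYC1 passed without shControl-1. The median of the oxidative phosphorylation list was -0.166 without shControl-1 and -0.266 without shGREM1-1.

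Among metabolic groups, hypoxia and glycolysis genes were lower. Of 34, 9 fell, 0 rose and 25 did not pass, and 14 fell and 1 rose adjusted over the list alone (median log2 fold change -0.286; limma adjusted p = 0.000197; adjusted p = 0.466 with an estimated correlation). The hexokinase gene HK2 fell from 42.7 ± 5.18 to 21.4 ± 3.24 CPM (SD, n = 2 each) and the carbonic anhydrase gene CA12 from 11.9 ± 0.872 to 4.89 ± 0.761 CPM, and PGK1 (-0.45) and TPI1 (-0.43) fell too. NRF2 and oxidative stress genes were lower, with 5 of 29 fallen and 9 adjusted over the list alone, and 0 risen (median -0.241; limma adjusted p = 0.000993; adjusted p = 0.466 with an estimated correlation). Those 5 were the metallothionein genes MT2A (1030 ± 130 to 480 ± 37.0 CPM) and MT1X, the heme oxygenase gene HMOX1 (-0.93), NQO1 (-0.55) and AKR1C1 (-0.97). The metallothionein and AKR1C genes have close paralogs, and AKR1C1 did not pass without shControl-1 or without shControl-2. Cholesterol and fatty acid synthesis genes were higher, with 2 of 32 risen, INSIG1 (0.81 ± 0.12), a feedback regulator of cholesterol synthesis, and LSS (0.45), and the same count adjusted over the list alone (median 0.212; limma adjusted p = 0.00476; adjusted p = 0.516 with an estimated correlation). That list was not called without shControl-2 (limma adjusted p = 0.0536) or without shGREM1-1 (0.122). LSS had an edgeR adjusted p of 0.0703 without shControl-1 and 0.155 without shControl-2, and 10 members rose without shGREM1-2. Of 37 genes of the unfolded protein response and ATF4, CEBPB (-0.64) and SESN2 (-0.55) fell, also adjusted over the list alone, and the list was not called (limma adjusted p = 0.326), except without shControl-1 (0.0094) and without shGREM1-1 (0.0317). Without shControl-1, 3 hypoxia and glycolysis genes fell and 3 NRF2 genes fell, MT1X had an edgeR adjusted p of 0.0633 and SESN2 of 0.0703. Without shControl-2, 3 NRF2 genes fell and NQO1 had an adjusted p of 0.0676, without shGREM1-2 8 NRF2 genes fell and SESN2 had 0.0509, and without shGREM1-1 7 genes of the unfolded protein response list fell. Of that list, 3 fell and 0 rose without shControl-1, 2 fell and 2 rose without shControl-2, and 3 fell and 4 rose without shGREM1-2. SESN2 did not pass after a length and GC correction (edgeR adjusted p = 0.0706). In the hypoxia and glycolysis list 1 gene rose without either shGREM1 library, in the NRF2 list 1 rose without shControl-2, and in the cholesterol list 1 rose without either shControl library.

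Growth signalling targets were lower as lists, although most members did not pass. Those that did not pass were 12 of 15 WNT, 16 of 21 YAP/TEAD and 20 of 25 MAPK genes. Of 15 WNT target genes, CCND1 (cyclin D1; 631 ± 20.2 to 301 ± 16.1 CPM; SD, n = 2 each), CD44 (292 ± 2.99 to 173 ± 7.11 CPM) and NKD1 fell, 0 rose, and 6 fell adjusted over the list alone (median log2 fold change -0.369; limma adjusted p = 0.00195; adjusted p = 0.466 with an estimated correlation). Of 21 YAP/TEAD targets, FOXF2 (-1.28 ± 0.12), GADD45A (-0.95), ANKRD1, F3 and AMOTL2 fell, 0 rose, and 8 fell and 1 rose adjusted over the list alone (median -0.273; limma adjusted p = 0.0133; adjusted p = 0.466 with an estimated correlation). Of 25 MAPK feedback and immediate early genes, CCND1, the AP-1 gene FOSL1 (-0.81 ± 0.12), IER3, ETV4 and EPHA2 fell, 0 rose, and 5 fell adjusted over the list alone (median -0.179; limma adjusted p = 0.00314; adjusted p = 0.51 with an estimated correlation). The MAPK list was not called without shGREM1-1 (limma adjusted p = 0.0736). Without shControl-1 or shControl-2, 3 MAPK genes fell, and without shGREM1-2 9 fell. YAP/TEAD falls numbered 2 without shControl-1 and 9 without shGREM1-1, 1 YAP/TEAD target rose without either shGREM1 library, and WNT falls 5 without shGREM1-1. Without shControl-1, ANKRD1 had an edgeR adjusted p of 0.0568, F3 of 0.0628 and ETV4 of 0.0835; without shControl-2, NKD1 had 0.221, F3 0.0618, IER3 0.142 and ETV4 0.0607; and without shGREM1-1 ETV4 had 0.0779.

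Angiogenesis genes were lower in shGREM1. Of 19 measured, 8 fell, 0 rose and 11 did not pass, with the same counts adjusted over the list alone (median log2 fold change -0.567; camera, limma adjusted p = 0.000143; adjusted p = 0.466 with an estimated correlation). The Notch ligand gene JAG1 (138 ± 1.34 to 69.3 ± 7.99 CPM; SD, n = 2 each), the neuropilin gene NRP1 (95.5 ± 12.3 to 53.7 ± 2.16 CPM), the placental growth factor gene PGF (26.5 ± 2.52 to 12.7 ± 0.743 CPM) and VEGFC (-0.82) were among them. Angiogenesis was the only one of the 34 lists that fry, a rotation test of each list by itself, called (limma adjusted p = 0.0445). The number of falls was 4 without shControl-1, where VEGFC had an edgeR adjusted p of 0.111, and 5 without shControl-2. Without shGREM1-1, 6 members fell and 2 rose.

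Extracellular matrix genes went both ways. Of 39, COL3A1, FBN1, COL16A1 (log2 fold change 0.64), LUM (0.64) and COL5A1 (0.51) rose, COL13A1 (-1.25 ± 0.12) and PLOD2 (-0.53) fell, 9 rose and 3 fell adjusted over the list alone, and the list was not called (limma adjusted p = 0.198). Proteases of the matrix and their inhibitors were lower as a list (median -0.394; limma adjusted p = 0.0259; adjusted p = 0.466 with an estimated correlation), with 5 of 23 fallen and 2 risen, and 6 and 3 adjusted over the list alone. ADAMTS12 (230 ± 17.5 to 150 ± 7.44 CPM; SD, n = 2 each), the urokinase receptor gene PLAUR (75.0 ± 0.695 to 48.7 ± 8.53 CPM) and MMP17 fell, as did MMP13 and MMP1 at under 3 CPM, while MMP24 (1.12) and MMP2 (0.41) rose. MMP9 had 117 and 113 CPM in shControl against 36.7 and 12.2 CPM in shGREM1 and did not pass (edgeR adjusted p = 0.254). The protease list was not called without shControl-2 (limma adjusted p = 0.0706), where 3 members fell, as also without shControl-1, while 9 fell without either shGREM1 library. MMP13 had an edgeR adjusted p of 0.126 without shControl-1 and MMP1 of 0.128 without shControl-2, and MMP13 had a DESeq2 adjusted p of 0.071. MMP1 overlaps WTAPP1 (1.46 CPM) and is uncertain. Of the proteases, 1 rose without shControl-1, shControl-2 or shGREM1-2. Matrix gene falls numbered 1 without shControl-1, 1 without shControl-2 and 5 without shGREM1-2.

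Regulators and markers of the epithelial-mesenchymal transition were not called (17 measured; limma adjusted p = 0.326), with SNAI2 lower and the epithelial adhesion gene EPCAM higher (log2 fold change 0.99 ± 0.22), over all genes and adjusted over the list alone. Of 13 stemness factors, the intermediate filament gene NES rose (1.04 ± 0.16) and the transporter gene ABCG2 fell at a low level, with the same 2 adjusted over the list alone (limma adjusted p = 0.385 for the list). Of 38 type I interferon response genes, SAMD9 (0.73) rose and IRF1 (-0.76), BST2 (-1.50), TRIM22 (-0.46) and IFITM3 (-0.42) fell, with 1 rise and 7 falls adjusted over the list alone (limma adjusted p = 0.0665 for the list). Antigen presentation genes were called lower (18 measured, median -0.175; limma adjusted p = 0.0162; adjusted p = 0.466 with an estimated correlation), although 0 members passed edgeR's test over all genes or over the list alone. Antigen presentation was not called without shGREM1-2 (limma adjusted p = 0.0722), where 2 members fell and 1 rose, 2 fell without shGREM1-1, and the interferon list was called without shGREM1-1 (0.01) and after a length and GC correction (0.0456). Without shControl-1, EPCAM had an edgeR adjusted p of 0.0912, ABCG2 of 0.0832 and IRF1 of 0.0728, and ABCG2 had 0.0601 without shControl-2. Of the interferon genes, 1 fell without shControl-1, 2 fell without shControl-2 and 2 rose without shGREM1-2. Of the stemness factors, 0 fell without either shControl library, and 2 rose and 3 fell without shGREM1-1. Of the transition genes, 2 rose and 2 fell without shGREM1-1, and 2 rose without shGREM1-2.

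Markers of other cell types were mostly low, with exceptions, and a few cartilage, muscle and epithelial genes differed. The keratin genes KRT8, KRT17 and KRT18 had means of 1500, 1010 and 609 CPM in shControl. SOX9, EGFL7 and TNNT1 had 233, 178 and 145 CPM there. Among 10 measured chondrocyte markers, the transcription factor gene SOX5 (log2 fold change 1.35 ± 0.16), HAPLN1 (45.6 ± 1.87 to 87.6 ± 3.71 CPM; SD, n = 2 each), the aggrecan gene ACAN (11.7 ± 1.01 to 21.3 ± 1.94 CPM) and SOX9 rose, COL9A2 (log2 fold change -0.62) fell, and 7 rose and 1 fell adjusted over the list alone (limma adjusted p = 0.02; adjusted p = 0.516 with an estimated correlation). The chondrocyte list was not called without shGREM1-2 (limma adjusted p = 0.27) or on ranks (0.0586). SOX9 had an edgeR adjusted p of 0.357 without shControl-1, 0.119 without shGREM1-2 and 0.0589 without robust estimation, and 0.0528 with limma-voom. Of 5 muscle markers TNNC1 (1.08) and TNNT2 rose, also adjusted over the list alone, and the list was not called (limma adjusted p = 0.101), with 1 rise without either shControl library. Of 14 epithelial markers, KRT8 (0.57), KRT18 (0.46) and EPCAM rose, and 4 rose adjusted over the list alone (limma adjusted p = 0.28 for the list); KRT8 and KRT18 overlap in the annotation, KRT8 had an edgeR adjusted p of 0.0876 without shControl-1 and 0.138 without shControl-2, and 0 epithelial markers rose without shControl-1 and 3 fell without shGREM1-2. Of 8 endothelial markers 0 passed, over all genes or over the list alone (limma adjusted p = 0.897). The adipocyte list was called lower (8 measured; limma adjusted p = 0.0444; adjusted p = 0.466 with an estimated correlation), with 1 fall, PLIN4, which overlaps the far more abundant HDGFL2 (94.1 CPM) and is uncertain, and 4 falls and 1 rise adjusted over the list alone, but not without shControl-1 (limma adjusted p = 0.0613), shControl-2 (0.0675) or shGREM1-2 (0.213), on ranks (0.0761) or after a length and GC correction (0.0716). PLIN4 had an edgeR adjusted p of 0.181 without shControl-1, 0.11 without shControl-2 and 0.136 without shGREM1-2, and it did not pass with DESeq2 (0.159), limma-voom (0.0592), no robust estimation (0.0537) or the correction (0.0707). Without shGREM1-1, 3 adipocyte markers fell and 1 rose, and without shGREM1-2 0 fell and 1 rose. The leukocyte and osteoclast list was called lower (5 measured; limma adjusted p = 0.0452; adjusted p = 0.516 with an estimated correlation), with 1 fall, OSCAR (11.4 ± 1.92 to 4.25 ± 0.232 CPM), and 2 adjusted over the list alone, but not without shControl-2 (limma adjusted p = 0.15), shGREM1-1 (0.122) or shGREM1-2 (0.0634, with 2 falls), on ranks (0.0694) or after a length and GC correction (0.0701). The leukocyte genes PTPRC and CD74 had mean levels of 0.453 and 1.04 CPM in shControl, beside the NF-kB genes that fell.

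**Figure D4:**
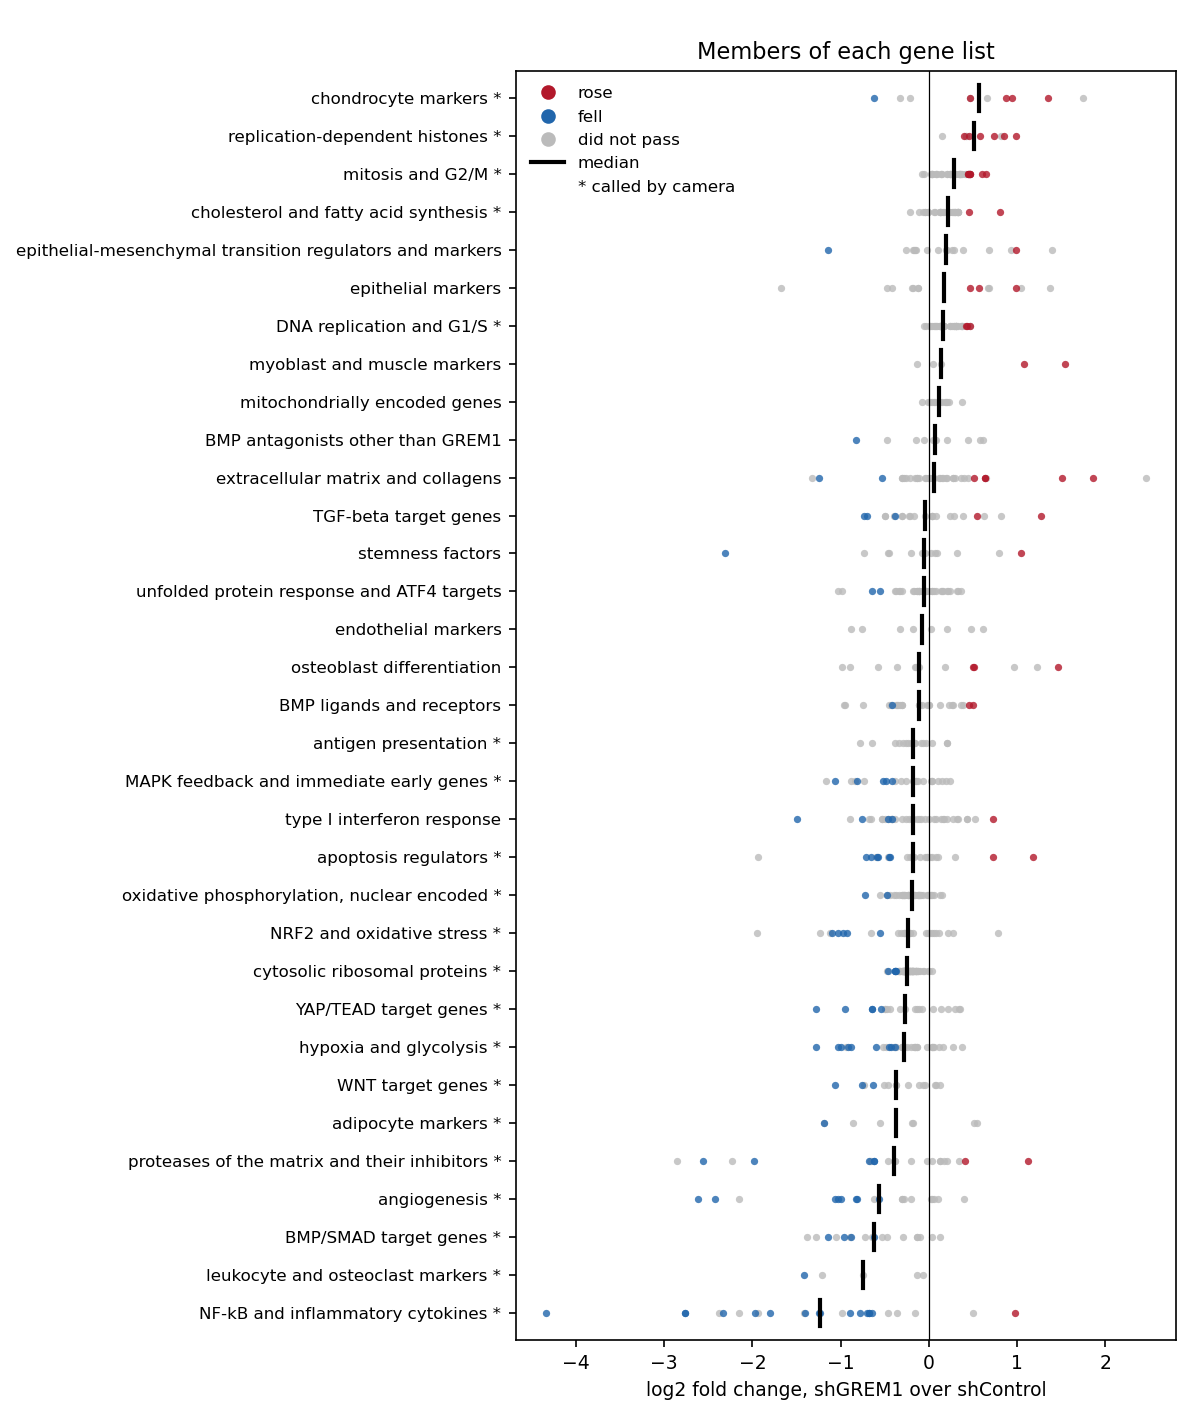
Log2 fold change of shGREM1 over shControl for each measured member of 33 of the 34 gene lists, sorted by list median (black bars). Red members rose, blue members fell and grey members did not pass; an asterisk marks the 20 of these lists called by camera with a preset correlation, from NF-kB and inflammatory cytokines (median -1.23) to chondrocyte markers (median 0.566).

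In all, camera called 21 of the 34 lists, 16 lower and 5 higher. With an estimated correlation 0 lists were called and 1 had an unadjusted p below 0.05, while fry called 1 list for movement in one direction and 27 for change in either direction. Of 881 genes on the lists, 40 were on more than 1 list. Across 11473 protein-coding genes with a mean CPM of 5 or more, log2 fold change had a Spearman correlation of 0.188 with gene length. With GC content it was -0.165. The corresponding values between libraries of one group were -0.174 and -0.161 for length and 0.342 and -0.127 for GC content. These correlations are across genes, which are not independent replicates.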

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

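The length and GC correction was chosen after seeing the results, and all other alternatives were fixed before. Of the 1418 changed genes, 1413 were also called with relative log expression scaling, 1290 with upper-quartile and 1321 with total count scaling, 987 with DESeq2, 1147 with limma-voom and 1237 after the length and GC correction, all in the same direction. The balance of higher and lower genes turned, from 659 and 759, to 793 and 631 with upper-quartile scaling, 709 and 663 with total count scaling, 708 and 688 with a mean CPM filter of 5 and 736 and 695 after the correction. The replicate block called 1101 higher and 1273 lower genes (at least 2-fold: 253 and 287), but same-numbered libraries did not deviate together (correlation -0.00703 over 18442 genes). Without a count filter 1142 genes were lower. With a mean CPM filter of 5, 90 genes were at least 2-fold higher and 83 lower. Against a fold of 1.5, glmTreat called 37 higher and 61 lower genes, of which 37 and 60 were at least 2-fold. Leaving out 1 library gave from 266 to 998 higher and from 382 to 1112 lower genes, and from 96 to 267 and from 135 to 326 at least 2-fold. Some of the 103 named genes that passed no longer did so when 1 library was left out, more of them without a shControl library. None changed direction, but this was largely fixed by how they were chosen. The largest rises and falls had no overlap between the groups, and the other genes had the smallest p of their lists in these same libraries. Of the 21 lists called, 0 were called with an estimated correlation, 1 by fry, 18 on ranks and 20 under the replicate block. The length and GC correction kept 19, lost the adipocyte (limma adjusted p = 0.0716) and leukocyte and osteoclast (0.0701) lists and gained the interferon list (0.0456). The sign of the list test, which need not be that of the list median, turned only in lists not called: TGF-beta targets by fry (median -0.0458), endothelial markers after the correction (-0.0907), and, without single libraries, BMP antagonists, osteoblast, unfolded protein response and mitochondrially encoded genes. Without single libraries the medians of these 4 ran from -0.17 to 0.064, -0.171 to 0.309, -0.208 to 0.0507 and -0.0506 to 0.268. The median also changed sign for stemness factors (0.0176 without shControl-1, 0.0239 after the correction), muscle markers (-0.0761 without shGREM1-2), endothelial markers (0.0409 without shControl-1, 0.0138 with DESeq2) and TGF-beta targets (0.0169 without shGREM1-1). Alternatives for the GREM1 fold change were not run, because no fold change could be given.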

Other observations

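The groups of transcripts and the tests in this part were chosen after seeing the results, except the length and GC test of the zinc finger genes, whose prediction was written before its result. Of 1123 kept long intergenic non-coding RNAs, 51 rose and 23 fell by edgeR's test, and of 14206 kept protein-coding genes 559 rose and 708 fell. After the length and GC correction the counts were 49 and 24 for the non-coding RNAs and 638 and 641 for protein-coding genes. Zinc finger genes with a ZNF or ZFP symbol, many of which encode DNA-binding proteins, were slightly higher in shGREM1: 330 of 462 kept genes lay above 0, 22 rose and 4 fell. Their median deviation was -0.106 and -0.056 in the shControl libraries and 0.089 and 0.0937 in the shGREM1 libraries.

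The lower NF-kB and cytokine genes were weighed against 3 possible causes. A trend of the libraries with gene length and GC content would end the difference once corrected, but the list median was -1.13 after the correction. RNA of leukocytes in shControl would bring abundant leukocyte transcripts, but the highest of 6 such transcripts had a mean of 1.04 CPM there, against 34 CPM for IL1B. A change of whole regions would lower the neighbours too, but the 297 nearest genes around the 15 fallen members had a median log2 fold change of 0.00125. This median pooled all the regions, so a change of a few of them would not show in it. It argues only against a loss shared by most of the regions. A difference in culture density or in the cells chosen for each line could give the same pattern and was not tested here.

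A trend of the libraries with gene length and GC content could also lower ribosomal protein and oxidative phosphorylation genes while it raises mitosis and replication genes. After the length and GC correction, 4 of the 4 lists were still called by camera with its preset correlation, with medians of -0.219 for ribosomal proteins, -0.208 for oxidative phosphorylation, 0.271 for mitosis and 0.214 for replication. With an estimated correlation these lists were not called even before the correction, so this test rests on the preset value.

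For the zinc finger genes, the same trend was not a sufficient cause, since their median lay 0.159 above that of protein-coding genes after the correction. A copy gain of the clusters on chromosome 19 would leave other zinc finger genes unchanged, but the 254 outside chromosome 19 had a median of 0.138, against 0.195 for the 208 on it. Only 8 other kept genes lay between zinc finger genes there, with a median of -0.183.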
